A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

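Budding yeast of the BY4741A background was grown in rich medium to exponential phase and fixed with formaldehyde, per the labels' protocols, chromatin was broken by bead beating and sonication, and libraries were made with an Illumina TruSeq DNA kit. The labels name homemade rabbit polyclonal antibodies for H3K4me2 and H3K4me3. The series lists 17 samples in 9 groups: 8 groups of 2 replicates from 4 genotypes and 2 antibodies, and 1 wild-type input. Groups and replicate numbers were taken from the sample titles. Peak lists of 4 samples were used, 1 in each of 4 groups. The other 13 samples, both Cps25 mutant genotypes among them, were not analysed here.

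Per the submitters' processing notes, the tools were Bowtie 1.1.2 and MACS2 2.1.1 and the genome build sacCer3. The notes give no order or settings, and whether the input served as the control is not given in the sources used here. Each list belongs to 1 library, so replicates were not pooled in it as far as the labels show. The authors deposited a score per peak without stating its scale, and it was used only to rank and filter peaks within a list. The H3K4me2 list of Cps25 wild-type cells also carries, per the file headers, a nearest gene, a distance to its start and a cluster number. For the cluster comparison a gene named for peaks of both clusters counted for cluster 1. The authors deposited gene ontology tables for both clusters with an enrichment ratio, the number of genes observed over the number expected, and a Fisher p-value for each term, which is not stated to be adjusted. Read depth is unknown for every library. The names of both wild-type lists say that set1 deletion peaks were taken out, and this was tested on the lists by overlap and by the gaps in the running numbers of the peak names.

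Genes came from the RefSeq table of assembly R64 of the same genome, with 6477 genes, 6002 of them nuclear and protein-coding and 275 nuclear tRNA genes. Strand was read from the systematic name, and the start is the start codon. Of the deposited distances to genes found in this table, 99.9% were met within 2 bp, which was the test that the builds match. No genome sequence was used. Chromosome lengths were taken from the last annotated feature or peak. Transposons, long terminal repeats, centromeres and telomeres were not analysed here.

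A gene counted as marked when a peak overlapped the first 500 bp of its ORF, or the whole ORF if shorter, by at least 1 bp. Overlaps of lists were set beside 1000 circular shifts of one list within each chromosome, and ranges give the central 95% of the shifted values. Each of 21 gene lists, written before the data were examined, was set beside 10000 random lists of the same size matched on ORF length in 10 classes, and a share below percentile 2.5 or above percentile 97.5 counts as outside. This describes these libraries and is not a test of the groups. Of the list members written down, 2 were not found in the gene table. Named genes follow a rule fixed before the data were examined: in each list and library up to 2 members with a 5′ peak of the highest score, up to 2 members with no peak over the ORF in alphabetical order, the genes at the 10 highest and 5 widest peaks of each library, and SET1 and SDC1. A few other genes were added after their values were seen: GAL3, GAL4 and GAL7, the members that complete a small count, and URA3, LEU2 and MET17 in the closing section, where HIS3, named by the rule, is also described. Shares carry exact Clopper-Pearson intervals at 95%.

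Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. The interval code was checked against bedtools 2.31.1 on 12 pairs of lists, with 0 pairs differing. The comparison with random lists was tested on simulated data over 6002 genes: of 200 lists of 50 genes drawn at a share of 40% where the rest had 70%, 97.5% were found, and 4.5% of unchanged lists were called. Alternatives fixed before the data were examined were the upper 50% of a list by score, peaks within 200 bp merged, an overlap of 50% of the peak or window, lists extended by 100 bp on each side, a window from 250 bp upstream to 500 bp downstream, the whole ORF, genes with a standard name, ORFs of at least 1000 bp, genes whose upstream neighbour lies on the same strand, and random lists not matched. The restrictions to genes and peaks away from set1 deletion peaks, and the cluster assignment by the deposited nearest gene, were added after seeing the data.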

Results

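Methylation of histone H3 on lysine 4 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in budding yeast, Saccharomyces cerevisiae, of the BY4741A background. Cells were taken in exponential growth in rich medium and fixed with formaldehyde. The series held 17 libraries. Of these, 16 came from 4 genotypes, each precipitated with an antibody against dimethylated lysine 4 (H3K4me2) and another against trimethylated lysine 4 (H3K4me3), with 2 replicates per group, and 1 was a wild-type input. The genotypes were wild-type Cps25, Cps25 with the A142D change, a deletion of CPS25 and a deletion of SET1. Set1 is the catalytic subunit of COMPASS and the methyltransferase that makes H3K4me1, H3K4me2 and H3K4me3 in this yeast. Cps25, encoded by SDC1, is the COMPASS subunit related to mammalian Dpy-30. The series title places the work in a study of how the complex of Ash2L and Dpy-30 shapes the H3K4 methylation states. Peak lists of 4 libraries were analysed, all of them replicate 1: H3K4me2 and H3K4me3 of Cps25 wild-type cells, and H3K4me2 and H3K4me3 of set1 deletion cells. The other 13 libraries, with both Cps25 mutant genotypes among them, were not analysed here. With 1 list per group there was no spread between replicates to estimate, so no p-value between groups is given and each difference describes these libraries. The read depth behind the peaks is unknown. The scores per peak are the authors' own, on a scale that is not given in the sources used here, and serve only to rank peaks within a list. Intervals in parentheses after a share are exact 95% intervals over genes or peaks and cover counting error only.

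SET1 (YHR119W, chromosome VIII, 346043 to 349285 in sacCer3) carried peaks of both marks over its start codon in Cps25 wild-type cells. Its H3K4me2 peak ran from 344917 to 346729, at score percentile 65.3 of the list, and its H3K4me3 peak from 345754 to 346551, at score percentile 56.6. Neither set1 deletion list held a peak at SET1, which checks nothing further, since the gene itself is deleted there. SDC1 (YDR469W, chromosome IV, 1399015 to 1399542), the gene of Cps25, had an H3K4me3 peak in wild-type cells from 1398988 to 1399439, at score percentile 8.32, and no listed H3K4me2 peak. In set1 deletion cells an H3K4me2 peak covered SDC1 from 1399054 to 1399515, at score percentile 24.5, and no H3K4me3 peak was listed there. Per their names, set1 deletion peaks were taken out of the wild-type lists, and H3K4me2 peak numbers were skipped at SDC1. Whether SDC1 carried H3K4me2 in wild-type cells is therefore open.

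Cells without Set1 give the background of both antibodies. Many of their peaks lay over genes for non-coding RNAs and over the ORFs of ribosomal proteins and glycolytic enzymes, groups known for very high transcription. Outside these groups, other ORFs held 257 of 874 nuclear H3K4me2 peaks (29.4%) and 284 of 735 nuclear H3K4me3 peaks (38.6%), and 131 and 44 peaks lay over none of these genes. Of 275 nuclear tRNA genes, 264 lay under a peak of the H3K4me2 antibody (96.0%, 93.0 to 98.0) and 259 under a peak of the H3K4me3 antibody (94.2%, 90.7 to 96.6). Small nucleolar RNA genes, which guide rRNA modification, were covered in 68 of 76 cases (89.5%, 80.3 to 95.3) and 54 of 76 cases (71.1%, 59.5 to 80.9). All 6 genes of spliceosomal small nuclear RNAs lay under an H3K4me2 peak and 5 of them under an H3K4me3 peak. The 3 genes of the RNAs of RNase P, RNase MRP and the signal recognition particle lay under peaks of both antibodies. Lists shifted at random along the chromosomes gave 1.45 to 5.45% of tRNA genes with the H3K4me2 antibody and 0.727 to 4.73% with the H3K4me3 antibody.

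The cytosolic ribosomal protein genes of the set1 deletion cells carried peaks over 97 of 138 ORFs with the H3K4me2 antibody (70.3%, 61.9 to 77.8) and over 69 with the H3K4me3 antibody (50%, 41.4 to 58.6). Shifted lists gave 2.90 to 11.6% and 2.17 to 10.1%. Glycolysis and fermentation ORFs lay under peaks in 11 and 13 of 20 cases (55.0% and 65.0%), against at most 25% after shifting, and translation factor ORFs in 11 of 25 cases with each antibody (44.0%), against at most 24.0%. Core histone ORFs were under H3K4me2 peaks in 4 of 8 cases and under H3K4me3 peaks in 0. Over all 6002 nuclear protein-coding ORFs, 405 (6.75%) and 329 (5.48%) lay under a peak, fewer than the 10.3 to 11.1% and 8.98 to 9.68% of shifted lists. The 12 annotated rRNA genes held 1 peak in each list, at the 5S rRNA gene RDN5-1 in the H3K4me2 list. Genes of ribosomal proteins and histones come in near-identical copies, so the copy that gave the reads is uncertain.

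**Figure D1:**
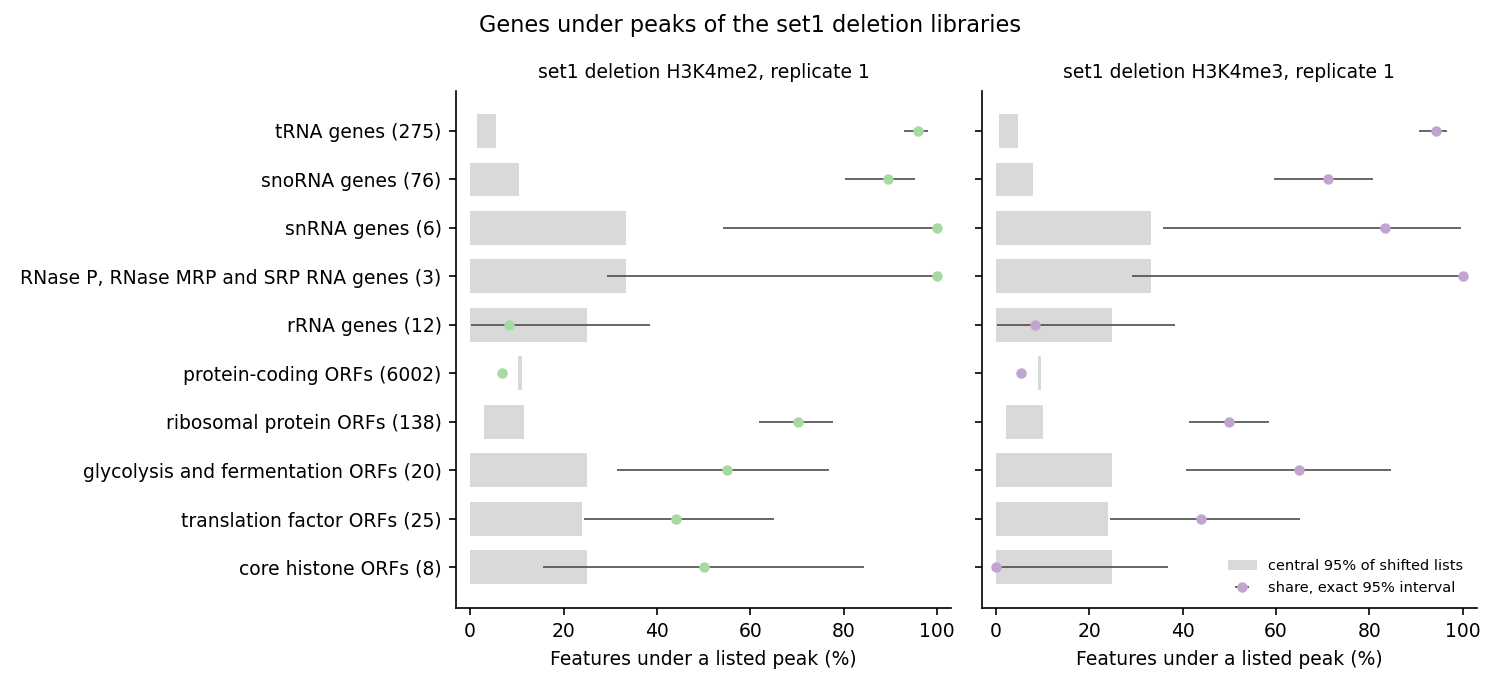
Share of each class of genes under a peak in the set1 deletion libraries (x axis, percent of genes, number of genes in parentheses), for H3K4me2 on the left and H3K4me3 on the right. Points give the share with its exact 95% interval and grey bars the central 95% of 1000 shifted lists; tRNA genes lie at 96.0% and 94.2%, above the shifted lists.

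Most of the highest peaks of the set1 deletion lists lay at genes transcribed by RNA polymerase III. With the H3K4me3 antibody the highest score was at SCR1, the RNA of the signal recognition particle (chromosome V, 441904 to 442617), followed by a tRNA gene on chromosome VII and by SNR52 (chromosome V, 431075 to 431481), and the remaining 7 of the top 10 were at tRNA genes, SUP61 and SUF6 among them. The top 10 of the H3K4me2 antibody held SCR1, SNR52, SUF5, EMT2, the 5S gene RDN5-1 and SNR17A, a U3 small nucleolar RNA gene. It also held the start of SWR1 (chromosome IV, 1135681 to 1136037) and 2 intervals with no gene of the gene table, on chromosome XIV from 771905 to 772406 and on chromosome IV from 449659 to 449888. The widest nuclear peaks lay along ORFs. YEF3, translation elongation factor 3, lay under 3323 bp of H3K4me2 peak (chromosome XII, 636729 to 640051) and 3119 bp of H3K4me3 peak. PMA1, the plasma membrane proton pump, lay under 2168 and 2039 bp, and PHO84, the high-affinity phosphate transporter, under 2119 and 1960 bp. ALD6, an acetaldehyde dehydrogenase, lay under 1969 and 1799 bp, and GCN4, the activator of amino acid biosynthesis genes, under 1814 bp of H3K4me3 peak next to a tRNA gene.

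Both antibodies marked many of the same places in cells without Set1. Of the 743 H3K4me3 peaks, 547 overlapped an H3K4me2 peak by at least 1 bp (73.6%, 70.3 to 76.8), against 3.63 to 7.13% of shifted lists. In the other direction 547 of 927 H3K4me2 peaks overlapped an H3K4me3 peak (59.0%, 55.8 to 62.2), against 3.02 to 5.61%. The peaks were narrow, with median widths of 276 bp (quartiles 190.5 and 375) and 269 bp (194 and 352.5), and covered 331 kb and 249 kb. Nuclear peaks over tRNA genes had median scores of 21.4 and 20.7 in the respective list, against 6.82 and 6.89 for those over ribosomal protein ORFs.

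Per their names, the wild-type lists had been filtered by taking out set1 deletion peaks, and this was checked on the lists. Within each antibody, 0 of 4393 H3K4me2 peaks and 0 of 4087 H3K4me3 peaks of Cps25 wild-type cells overlapped a set1 deletion peak. Shifted lists gave 6.28 to 7.49% and 4.70 to 5.90%. This absence of overlap follows from the filter and is no result about the marks. No tRNA gene lay under a wild-type peak, 0 of 275 with either antibody, the 11 and 16 tRNA genes with no set1 deletion peak of the same antibody included. For the tRNA genes under a set1 deletion peak the filter largely fixed this in advance. Numbers in the peak names were skipped at 291 places of the H3K4me2 list, and a set1 deletion H3K4me2 peak lay in 291 of these 291 intervals, against 7% of 4086 intervals without a skip. For H3K4me3 the counts were 230 of 230 and 7.34% of 3841. In all, 354 of 4747 H3K4me2 peak numbers and 258 of 4345 H3K4me3 peak numbers were absent. Where a gene close to a set1 deletion peak has no listed wild-type peak, the lists leave open whether the gene carried the mark, and for the lists most concerned the number of genes near such peaks is given. The filter acted per antibody, and 131 wild-type H3K4me3 peaks still overlapped a set1 deletion H3K4me2 peak, as did 59 wild-type H3K4me2 peaks a set1 deletion H3K4me3 peak.

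In Cps25 wild-type cells H3K4me3 lay nearly everywhere inside H3K4me2. The H3K4me2 list held 4393 peaks with a median width of 683 bp (quartiles 586 and 798), covering 3120 kb, and the H3K4me3 list 4087 peaks with a median width of 598 bp (457 and 706), covering 2450 kb. Of the H3K4me3 peaks, 3920 overlapped an H3K4me2 peak (95.9%, 95.3 to 96.5), against 42.2 to 45.2% of shifted lists. Of the H3K4me2 peaks, 3762 overlapped an H3K4me3 peak (85.6%, 84.6 to 86.7), against 38.5 to 41.2%. By length, 95.4% of the H3K4me3 bases lay under H3K4me2 and 74.9% of the H3K4me2 bases under H3K4me3.

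The highest H3K4me2 peaks by score lay over the starts of SYG1, TAL1 (transaldolase), HAC1 (the transcription factor of the unfolded protein response), ERV46, HST3 (a histone deacetylase of the sirtuin family), PDB1 (pyruvate dehydrogenase), RPN12 (proteasome), PGA1 with IGO1, BGL2 and ADK1 (adenylate kinase). SYG1 led with a peak of 1106 bp on chromosome IX, 266822 to 267927. For H3K4me3 they were SLA2, RPL35B, STM1, CCW14, PUP1 (proteasome), SEC13, RVB1, CCR4, RSC2 and SEC61. SLA2, an actin-binding protein of endocytosis, led with a peak of 728 bp on chromosome XIV, 187950 to 188677. No gene stood in both top 10 lists. The widest peaks joined several starts. An H3K4me2 peak of 2824 bp (chromosome X, 468842 to 471665) held the starts of REC107, LSM8 and MDE1, and the others of the widest 5 held those of CUE2, CSM1 with ABP1, AIM20 with UBP7, and DUT1 with SRB6. The widest H3K4me3 peak, 2145 bp on chromosome XII from 182861 to 185005, held the starts of YEH2, IRC25 and SDO1, and the next ones those of RPT4 with GCD1, TYS1 with TFG1, MED6 with VMA22, and AIM46 with RPN10.

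Listed peaks of both marks sat at the 5′ ends of genes, and those of H3K4me2 reached further into the ORF. Among 6002 nuclear protein-coding genes, 4506 had an H3K4me2 peak in the first 500 bp of the ORF (75.1%, 74.0 to 76.2) and 4126 an H3K4me3 peak (68.7%, 67.6 to 69.9), against 285 (4.75%) and 204 (3.40%) in set1 deletion cells. Both marks were listed at 3975 genes, H3K4me2 alone at 531, H3K4me3 alone at 151 and neither at 1345. Among the 5209 genes with no set1 deletion peak from 500 bp upstream to 1000 bp downstream of the start codon, a restriction chosen after seeing the data, the counts were 3742, 439, 16 and 1012. Coverage by H3K4me2 peaks was highest at 74.5% between 100 and 200 bp after the start codon and was 48.1% between 500 and 600 bp, and H3K4me3 gave 67.8% and 27.1% in the same steps. In the 3975 genes with both marks the H3K4me2 peak ended at a median of 585 bp after the start codon and the H3K4me3 peak at 494 bp. The H3K4me2 peak ended further downstream in 3757 of these genes (94.5%), with a median difference of 82 bp (95% interval over genes 79 to 85, quartiles 42.5 and 137). The H3K4me2 peak also started further upstream in 3065 of these genes (77.1%), with a smaller median difference of 17 bp, so it was wider on both sides. The peak centres lay at 231.5 and 194 bp. Each mark had 1 library of unknown read depth, so whether depth or enrichment moved the peak edges cannot be told. In ORFs of at least 1000 bp, H3K4me2 peaks covered on average 78.9% of the bases in the first 10% of the ORF and 2.28% in the last 10%.

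**Figure D2:**
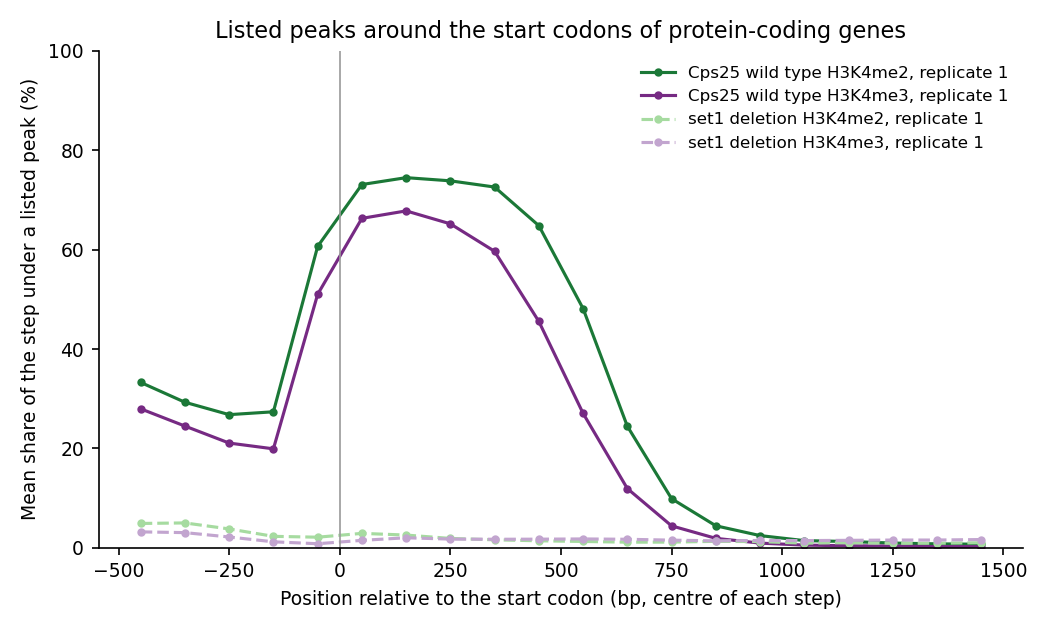
Mean share of each 100 bp step under a listed peak (y axis, percent) by its distance from the start codon (x axis, bp) over nuclear protein-coding genes long enough to hold the step, for replicate 1 of the 4 groups. The H3K4me2 curve reaches 74.5% and the H3K4me3 curve 67.8% between 100 and 200 bp in Cps25 wild-type cells, while both set1 deletion curves stay near the axis.

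Genes for making ribosomes, for respiration and for protein breakdown carried the marks more often than random gene lists matched on ORF length. Of 81 ribosome biogenesis genes, 73 had an H3K4me2 peak (90.1%, 81.5 to 95.6; random lists 71.6 to 87.7%) and 77 an H3K4me3 peak (95.1%, 87.8 to 98.6; random lists 64.2 to 82.7%). Among genes with a standard name the H3K4me2 share of this list was within the random lists (74.1 to 90.1%), the only one of the 7 other settings in which its excess was lost. NOG1, a nucleolar GTPase of 60S assembly (YPL093W), and HAS1, an RNA helicase (YMR290C), had the highest H3K4me2 scores of the list, at percentiles 99.3 and 99.2, and UTP15 and GAR1 the highest H3K4me3 scores, at 99.6 and 98.6. DBP2 and NOG2 had no listed peak of either mark and each carried a set1 deletion peak. In set1 deletion cells 6 and 3 of the 81 genes had a peak. Of 47 genes of mitochondrial respiration and the TCA cycle, 45 had an H3K4me2 peak (95.7%, 85.5 to 99.5; random lists 53.2 to 78.7%) and 43 an H3K4me3 peak (91.5%, 79.6 to 97.6; random lists 46.8 to 72.3%), against 1 and 0 in set1 deletion cells. ATP2 and ATP1, subunits of the mitochondrial ATP synthase, led the H3K4me2 and H3K4me3 members at percentiles 99.5 and 96.4, and CYC7, an isoform of cytochrome c used at low oxygen, had no peak of either mark. Of 32 proteasome genes, 31 had a peak of each mark (96.9%, 83.8 to 99.9), above the random lists at 62.5 to 90.6% and 53.1 to 84.4%, against 0 and 1 in set1 deletion cells. RPN12 and RPT1 of the regulatory particle led for H3K4me2 (99.9 and 98.7), and PUP1 and RPN6 for H3K4me3 (99.9 and 99.7). PRE1 lacked a listed H3K4me2 peak. RPN5 lacked a listed H3K4me3 peak and carried a set1 deletion H3K4me3 peak over its ORF.

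Subunits of RNA polymerases I and III had peaks of each mark in 18 of 20 genes (90%, 68.3 to 98.8), which was above the random lists for H3K4me3 (45.0 to 85.0%) and within them for H3K4me2 (50 to 90%). The H3K4me3 excess was lost among genes with a standard name, and the H3K4me2 share passed the random lists in 3 of the 7 other settings. RPC82 (H3K4me2, percentile 99.1) and RPC40 (H3K4me3, 95.8) led. RPA12 had neither mark listed and carried set1 deletion peaks of both antibodies. Cyclins and cell cycle regulators had an H3K4me2 peak in 22 of 23 genes (95.7%, 78.1 to 99.9; random lists 60.9 to 95.7%, percentile 97.9) and an H3K4me3 peak in 20 (87.0%, 66.4 to 97.2), within the random lists. The H3K4me2 excess of this list was lost in 4 of the 7 other settings tried. NRM1 and SWI5, transcriptional regulators, led for H3K4me2, SIC1, the inhibitor of cyclin-dependent kinase, led for H3K4me3, and the cyclin gene PCL1 had neither mark listed. Neither group stood out in set1 deletion cells, with 1 and 2 of 20 genes and 0 and 0 of 23.

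Genes of meiosis and of the subtelomeric families carried the marks less often than random lists. Of 56 genes of meiosis and sporulation, 3 had an H3K4me2 peak (5.36%, 1.12 to 14.9; random lists 66.1 to 87.5%) and 2 an H3K4me3 peak (3.57%, 0.435 to 12.3; random lists 58.9 to 82.1%), and 53 had neither. Over the whole ORF the counts were 8 (14.3%) and 4 (7.14%), and with 50% of the window covered 1 and 1 (1.79%), below the random lists in each case. The members listed first were REC107 and MER1. The REC107 H3K4me2 peak was the widest of the list and also held the starts of its neighbours, and the MER1 peaks covered 69 and 21 of the 500 bp tested. AMA1, an activator of the anaphase-promoting complex in meiosis, and CST9 had no peak. Of 47 genes in the list of the subtelomeric families PAU, COS and FLO, 2 had an H3K4me2 peak (4.26%, 0.520 to 14.5; random lists 48.9 to 74.5%) and 0 an H3K4me3 peak (0 to 7.55%; random lists 42.6 to 68.1%). Not all of the 47 lie near a chromosome end: COS111, on chromosome II from 629168 to 631942, was counted among them. The H3K4me2 peaks were at COS9 and COS10, at percentiles 6.19 and 3.37. Members of these families share sequence, which can leave their reads unplaced. None of these 47 genes had a set1 deletion peak near its start, and 8 of the 56 meiosis genes did.

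Among 7 galactose genes, GAL80, which encodes the repressor of the pathway, had peaks of both marks (percentiles 30.2 and 32.0), and GAL1, GAL2, GAL3, GAL4, GAL7 and GAL10 had none in this window, against random lists at 57.1 to 100% and 42.9 to 100%. Over the whole ORF 3 of the 7 genes had an H3K4me2 peak (42.9%) and 2 an H3K4me3 peak (28.6%), still below the random lists. Of 18 hexose transporter genes, 3 had an H3K4me2 peak (16.7%, 3.58 to 41.4; random lists 61.1 to 94.4%) and 1, the glucose sensor RGT2, an H3K4me3 peak (5.56%, 0.141 to 27.3; random lists 50 to 94.4%). HXT3 had an H3K4me2 peak at percentile 4.05, and HXT1 and HXT10 had neither mark listed. HXT1 carried set1 deletion peaks of both antibodies, so whether it had the marks is open. Several HXT genes are close copies of each other, and 7 of the 18 had a set1 deletion peak near the start. None of 5 alpha-cell-specific genes had a listed peak (0 to 52.2%; random lists 20 to 100% for each mark), a deficit that was lost for both marks in the upper 50% by score. In set1 deletion cells MF(ALPHA)1 and MF(ALPHA)2, the alpha-factor genes, had H3K4me2 peaks, and MF(ALPHA)1 an H3K4me3 peak at percentile 67.7. Whether these 2 genes carried H3K4me2 in wild-type cells is therefore open, as is H3K4me3 at MF(ALPHA)1. The other 3 genes, with no set1 deletion peak near the start, had neither mark listed, still below the random lists. The list of a-cell-specific and haploid-specific genes had H3K4me2 peaks in 13 of 16 cases (81.2%, 54.4 to 96.0) and H3K4me3 peaks in 10 (62.5%, 35.4 to 84.8), within the random lists. Its a-cell-specific and haploid-specific members were not counted apart, so it gives no comparison of a-cell-specific with alpha-cell-specific genes. STE5, the scaffold of the pheromone kinase cascade, led both marks. HO and MFA1 had no H3K4me2 peak, and AGA2 and ASG7 had no H3K4me3 peak.

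Ribosomal protein and glycolysis genes had listed wild-type peaks less often than random lists and set1 deletion peaks more often. Of 138 cytosolic ribosomal protein genes, 36 had an H3K4me2 peak (26.1%, 19.0 to 34.2; random lists 64.5 to 78.3%) and 68 an H3K4me3 peak (49.3%, 40.7 to 57.9; random lists 58.0 to 72.5%). In set1 deletion cells 93 (67.4%, 58.9 to 75.1) and 65 (47.1%, 38.6 to 55.8) had a peak in the same window, and 113 of the 138 had a set1 deletion peak near the start. In the upper 50% of the lists by score the H3K4me2 share stayed below the random lists, and the H3K4me3 share (60 genes, 43.5%) was within them and above their median. In the other 25 genes both marks were listed at 22 (88.0%, lower limit 68.8), which for H3K4me2 lay within the random lists (64 to 92.0%) and for H3K4me3 at percentile 98.2 of them. RPL35B (YDL136W, chromosome IV, 217600 to 218367) had the highest scores of both marks, at percentile 98.5 for H3K4me2 and the second highest of the whole list for H3K4me3. The next H3K4me2 member, RPL11B, had 17 bp of its 500 bp under a peak that lay mostly downstream. RPL31B was next for H3K4me3 (99.7), and RPL10 and RPL12A had neither mark listed. Of 20 glycolysis and fermentation genes, 5 had an H3K4me2 peak (25%, 8.66 to 49.1; random lists 60 to 95%) and 2 an H3K4me3 peak (10%, 1.23 to 31.7; random lists 50 to 90%), against 10 and 9 in set1 deletion cells. PFK2 and PFK1, the phosphofructokinase subunits, had H3K4me2 peaks at percentiles 99.0 and 98.4. ADH1 and CDC19 (pyruvate kinase) had neither mark listed, and FBA1 (aldolase), ADH1, CDC19 and TDH3 led the set1 deletion peaks. Among the 7 genes with no set1 deletion peak near the start, 3 had an H3K4me2 peak and 1 an H3K4me3 peak, below the random lists.

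Translation elongation and initiation factors had an H3K4me2 peak in 12 of 25 genes (48.0%, 27.8 to 68.7; random lists 60 to 92.0%) and an H3K4me3 peak in 16 (64%, 42.5 to 82.0), within the random lists, against 6 and 4 genes in set1 deletion cells. TIF4631 (eIF4G) and PRT1 (an eIF3 subunit) led for H3K4me2, and EFB1 and EFT1, elongation factors, had no listed H3K4me2 peak. Without the 9 genes near set1 deletion peaks, 11 of 16 had an H3K4me2 peak, within the random lists, as were the 11 of 25 with a peak in the upper 50% by score. Of 8 core histone genes, 1 had an H3K4me2 peak (HTA2, 12.5%, 0.316 to 52.7; random lists 25 to 87.5%) and 2 an H3K4me3 peak (HTB2 and HTB1, 25%, 3.19 to 65.1, at percentile 3.02 of the random lists), with score percentiles between 2.35 and 4.12. The H3K4me3 share was within the random lists in this setting and below them in 5 of the 7 others. In set1 deletion cells 4 and 0 histone genes had a peak in this window, and 5 of the 8 had a set1 deletion peak near the start. Of the other 3 genes 1 had an H3K4me2 peak, within the random lists.

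**Figure D3:**
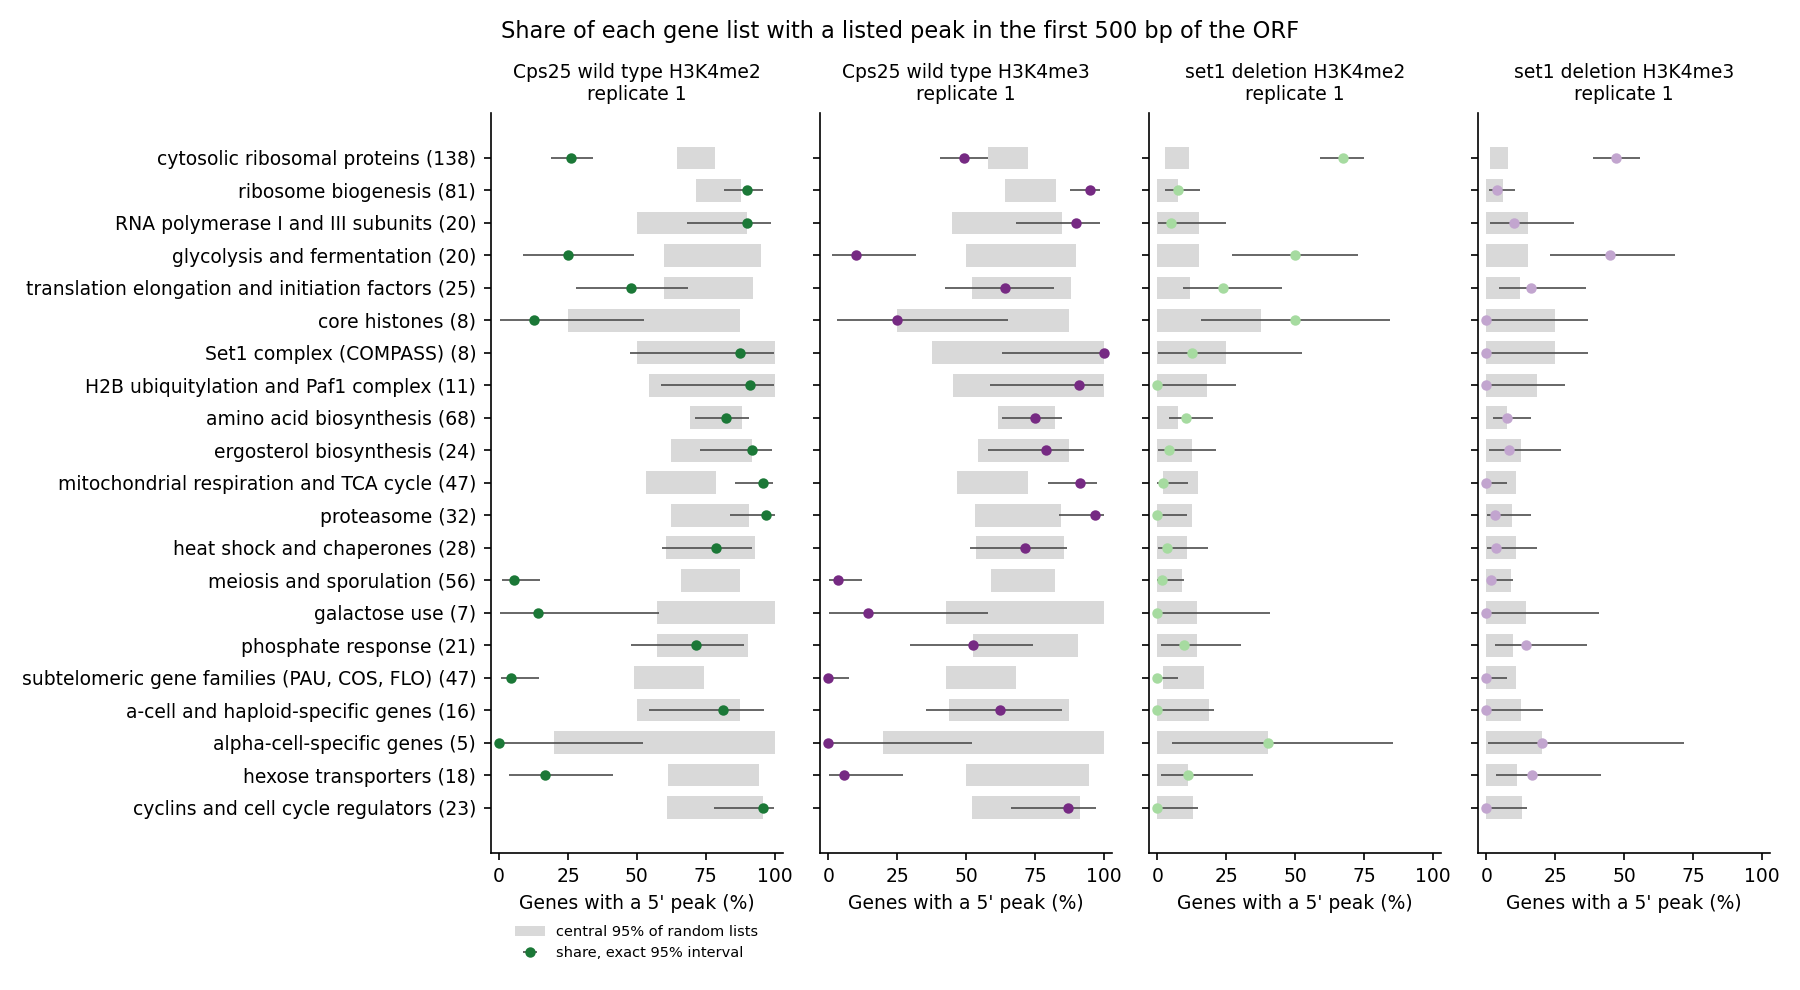
Share of the genes of each of the 21 lists with a listed peak in the first 500 bp of the ORF (x axis, percent, list size in parentheses), for replicate 1 of each group. Points give the share with its exact 95% interval and grey bars the central 95% of 10000 random lists matched on ORF length; ribosomal protein genes lie at 26.1% and 49.3% in wild-type cells and at 67.4% and 47.1% in set1 deletion cells.

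The remaining lists lay within the random lists for both wild-type marks in the first 500 bp of the ORF, and some of them passed the limits in other settings. The COMPASS subunit genes had an H3K4me2 peak in 7 of 8 cases and an H3K4me3 peak in 8 of 8, SWD2 leading both marks, and SDC1 alone had a set1 deletion peak. The list of H2B ubiquitylation and Paf1 complex genes, on which H3K4 methylation depends, also held JHD2, the gene of an H3K4 demethylase. Each mark was listed at 10 of its 11 genes, all but JHD2, and 0 of 11 had a set1 deletion peak. In the upper 50% by score the list lay above the random lists with 10 and 9 genes. BRE1 and PAF1 led its scores. Amino acid biosynthesis genes had H3K4me2 peaks in 56 of 68 cases (82.4%, 71.2 to 90.5) and H3K4me3 peaks in 51 (75%, 63.0 to 84.7), THR1 and BAT1 leading and ARG1 and ARG3 without either, against 7 and 5 in set1 deletion cells. Without the 14 genes near set1 deletion peaks the H3K4me2 share was above the random lists, at 51 of 54 (94.4%; random lists 72.2 to 92.6%). Ergosterol genes had them in 22 and 19 of 24 cases (91.7% and 79.2%), ERG20 and MVD1 leading, against 1 and 2, and without the 6 genes near set1 deletion peaks all 18 had H3K4me2 peaks, above the random lists. Heat shock and chaperone genes had them in 22 and 20 of 28 (78.6% and 71.4%), MDJ1 and FES1 leading and HSP12 without either, against 1 and 1. Phosphate response genes had them in 15 and 11 of 21 (71.4% and 52.4%), PHO86 and VTC4 leading and PHM7 without either, against 2 and 3. In all, 13 of 21 lists lay outside the random range for H3K4me2, 4 above and 9 below. For H3K4me3 it was 11, 4 above and 7 below. No adjustment was made for the number of lists, and by chance about 1 of the 21 would lie outside. Away from set1 deletion peaks 13 and 12 lists lay outside. Ribosomal proteins, translation factors and core histones were then no longer below for H3K4me2, nor were ribosomal proteins for H3K4me3.

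The deposited H3K4me2 table splits the peaks into clusters 1 and 2. Genes for protein synthesis and breakdown that had a listed peak were mostly in cluster 1. The comparison by gene list was chosen after the clusters were seen, and how the authors made them is not given in the sources used here. Cluster 1 held 829 peaks, with a median width of 783 bp, a median score of 41.6 and an H3K4me3 peak over 790 of them (95.3%, 93.6 to 96.6). Cluster 2 held 3564 peaks, with a median width of 662 bp, a median score of 30.3 and an H3K4me3 peak over 2972 (83.4%, 82.1 to 84.6). By the peak in the first 500 bp of the ORF, 863 of 4506 genes were in cluster 1 (19.2%). The share was 30 of 31 for proteasome genes (96.8%, 83.3 to 99.9), 33 of 36 for ribosomal protein genes (91.7%, 77.5 to 98.2), 11 of 12 for translation factors (91.7%, 61.5 to 99.8) and 57 of 73 for ribosome biogenesis genes (78.1%, 66.9 to 86.9). It was 11 of 18 for RNA polymerase I and III subunits (61.1%, 35.7 to 82.7) and 6 of 10 for H2B ubiquitylation and Paf1 genes (60%, 26.2 to 87.8). All 6 lists lay above random lists of the same size. Most of the 863 genes in cluster 1 were in none of these 6 lists. The ribosomal protein share covers only the 36 of 138 genes with a listed H3K4me2 peak. Cyclins and cell cycle regulators lay below them, with 0 of 22 genes in cluster 1 (0 to 15.4%; random lists 4.55 to 36.4%). Genes of mitochondrial respiration were split like the rest, with 8 of 45 in cluster 1 (17.8%, 8 to 32.1), as were amino acid biosynthesis genes, with 7 of 56 (12.5%, 5.18 to 24.1).

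**Figure D4:**
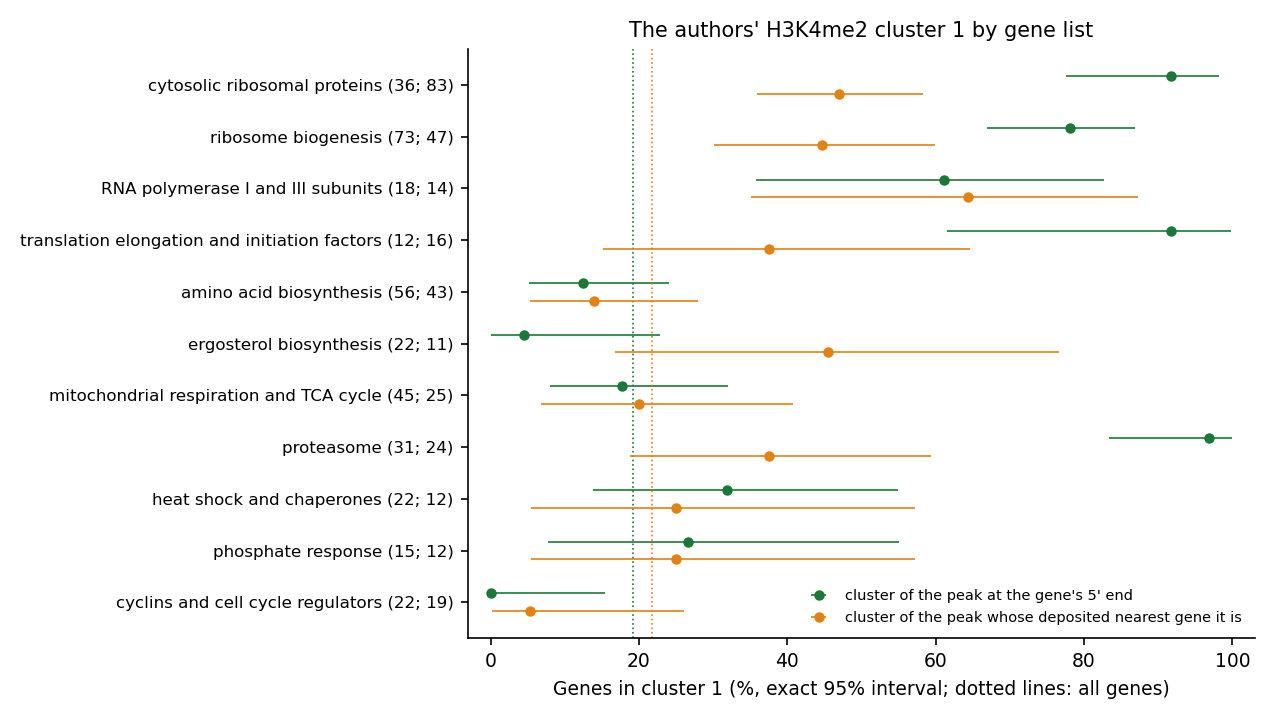
Share of the genes of a list in the authors' cluster 1 (x axis, percent, with exact 95% intervals), for the 11 lists with at least 10 genes under each assignment (numbers of genes in parentheses). Green points use the peak at the 5′ end of the gene and orange points the nearest gene of the deposited table, dotted lines mark all genes, and the proteasome list lies at 96.8% and 37.5%.

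The nearest gene named in the deposited table was seldom the gene under the peak. Of the 4393 H3K4me2 peaks, 3993 held at least 1 start codon (90.9%), and the deposited nearest gene was among those inside the peak in 4 of them. With genes assigned by the deposited name, 39 of 83 ribosomal protein genes (47.0%, 35.9 to 58.3) and 21 of 47 ribosome biogenesis genes (44.7%, 30.2 to 59.9) were in cluster 1, still above random lists, as were RNA polymerase I and III subunits with 9 of 14 (64.3%, 35.1 to 87.2). Proteasome genes, with 9 of 24 (37.5%, 18.8 to 59.4), and translation factors, with 6 of 16 (37.5%, 15.2 to 64.6), were within them, as were H2B ubiquitylation and Paf1 genes with 1 of 6 (16.7%, 0.421 to 64.1).

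The authors' deposited tables of gene ontology terms may rest on the deposited nearest genes, which were seldom the genes under the peaks. The terms therefore need not describe genes that carry H3K4me2 peaks. For cluster 1 the table lists 59 terms, headed by translation, with 82 of 346 annotated genes against 41 expected (Fisher p 1.02e-10). Further terms of the authors' deposited table, picked here and not the next in rank, include ribosome biogenesis with 44 of 179 genes against 21.2 expected (Fisher p 1.06e-06). Others picked are rRNA processing with 29 of 123 (p 0.000169), tRNA aminoacylation with 11 of 40 (p 0.00539) and regulation of transcription elongation with 8 of 15 (p 0.000111). The authors' deposited table for cluster 2 lists 21 terms, with p 0.000436 as the smallest for single-organism metabolic process, and names endoplasmic reticulum organization with 9 of 9 genes (p 0.000769), the response to endoplasmic reticulum stress with 31 of 45 (p 0.00105) and actin cortical patch assembly with 9 of 10 (p 0.00457). Across both of the authors' deposited tables, 1 term was shared, cellular biosynthetic process, and the p-values are not stated to be adjusted for the number of terms.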

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

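The tests of ORF length, of the overlap of H3K4me3 peaks with set1 deletion peaks and of the genome build were chosen after the results they measure were seen, the others before, and the rule for the interval of the weak peaks was set after their ranks were seen.

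Mitochondrial DNA, which carries no histones, held 53 peaks of the H3K4me2 antibody and 8 peaks of the H3K4me3 antibody in the set1 deletion lists, where the wild-type lists held 0; this signal lies outside the comparisons of the report, no peak number was skipped in the wild-type lists at the place of that chromosome, and whether the lists treated it alike is open.

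Ribosomal protein genes rarely carried a listed H3K4me2 peak in wild-type cells, at 36 of 138. Short ORFs are argued against, since 26.1% lies below the 64.5 to 78.3% of random lists matched on ORF length. Removal of peaks that overlap set1 deletion peaks is a candidate cause: 99 of the 102 genes without a peak (97.1%) lay where peak numbers were skipped, against 29.5% of 1394 other genes without a peak. Little H3K4me2 at these genes in the cells stays open, because only 28 ribosomal protein genes had no set1 deletion H3K4me2 peak nearby, and their share with a peak (85.7%, 67.3 to 96.0) could not be set apart from the 80.4% of other genes. What the removed peaks held above the background of set1 deletion cells is not known from these lists.

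A second pattern, 167 H3K4me3 peaks with no H3K4me2 peak, goes against the near-complete nesting of the marks. Most may be owed to the same filter, since 122 of them (73.1%) overlapped a set1 deletion H3K4me2 peak where H3K4me2 peak numbers were skipped. Of the other H3K4me3 peaks, 0.179% overlapped such a peak at all. The filter keeps this second share low by construction, because listed H3K4me2 peaks overlap no set1 deletion H3K4me2 peak. The contrast therefore adds no support. Of the 43 that overlapped no set1 deletion H3K4me2 peak, 12 were in the lowest 10% of the list by score (27.9%, 15.3 to 43.7). That interval lies neither above 50% nor below 20%, so weak peaks near the calling threshold stay open for part of them. No biological explanation was tested.

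The third pattern is that the nearest gene of the deposited H3K4me2 table lies outside the peak although the peak holds another start. Another build is argued against for genes found in the gene table, since 99.9% of 4020 deposited distances were met within 2 bp. These were 4020 of 4393 peaks (91.5%). The other peaks name genes absent from the gene table, so their distances could not be checked and another annotation stays open. A search that skips starts inside the peak is a candidate cause: in 3611 of 3993 peaks (90.4%) the deposited gene was the closest start outside, and in 99.4% of the 3634 peaks whose deposited gene is in the gene table, a restriction made after the first value was seen. The gene ontology tables may rest on these names, because the expected counts imply 3.81 times as many genes in cluster 2 as in cluster 1, closer to the ratio of the nearest genes (3.80) than to that of the genes under the peaks (4.06). No biological explanation applies to this pattern.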

How the results depend on the processing

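The restrictions to places away from set1 deletion peaks and the assignment by deposited nearest gene were chosen after seeing the data; for values that moved, the cause was not tested unless the setting itself removes peaks. No paired analysis was possible because the groups share replicate numbers in the labels but only replicate 1 of each was analysed here. The upper 50% by score left 2197 and 2044 wild-type and 464 and 372 set1 deletion peaks (H3K4me2, H3K4me3), genes with a 5′ peak at 40.7% and 36.6%, and overlaps of 87.1% (H3K4me3 in H3K4me2), 80.2% (the reverse) and 89.2% (set1 deletion). An overlap of 50% of the peak gave 80.8% of H3K4me2 peaks with H3K4me3 and 68.6% for set1 deletion. Lists extended by 100 bp gave 96.6% and 87.7% in wild type, and 188 H3K4me2 and 109 H3K4me3 wild-type peaks then met set1 deletion peaks. Away from set1 deletion peaks the wild-type overlaps were 98.9% and 86.7%, and genes with a peak 80.3% (H3K4me2) and 72.1% (H3K4me3). The window from 250 bp upstream gave 76.3% and 70.3%, a covered window of 50% gave 71.9% and 63.4%, and genes with a standard name gave 80.1% and 74.2%. By deposited nearest gene, cluster 1 held 47.0% of ribosomal protein, 44.7% of ribosome biogenesis and 37.5% of proteasome genes, and 4 lists in place of 7 lay outside the random range. The ribosomal protein list reversed in sign, not to an opposite call except for H3K4me3 away from set1 deletion peaks: away from set1 deletion peaks its share lay 8 points above the median random list for H3K4me2 and 16 points above it for H3K4me3 (differences of -45.7 and -15.9 points in the report), and with the upper 50% by score 7.97 points above for H3K4me3. Of the comparisons of a leading result with an alternative, 29 moved and 29 stayed within their interval or count. Of the comparisons of a gene list with an alternative, 262 kept their call, 18 passed the limit of the random lists and 11 no longer did. Calls were lost in some setting for ribosomal proteins (both marks), for cyclins, ribosome biogenesis, translation factors, core histones and alpha-cell genes (H3K4me2) and for alpha-cell and RNA polymerase genes (H3K4me3). They were gained for RNA polymerase, Paf1, amino acid and ergosterol genes (H3K4me2) and for core histones, cyclins, COMPASS, Paf1 and phosphate genes (H3K4me3). The end of H3K4me2 beyond H3K4me3 stayed within its interval in all 3 restricted gene sets. Read depth is unknown, so what it limits cannot be stated.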

Other observations

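The genes described here were grouped or chosen after the lists were seen. Genes near chromosome ends had listed peaks of the marks less often than other genes, and the cause was not tested. Within 20 kb of an end, 48 of 251 genes had an H3K4me2 peak (19.1%, 14.4 to 24.5) and 32 an H3K4me3 peak (12.7%, 8.89 to 17.5). Between 20 and 40 kb it was 182 and 159 of 288 genes (63.2% and 55.2%), and further inside 4276 and 3935 of 5463 (78.3% and 72.0%). Among genes with a standard name the shares within 20 kb were 23.3% and 17.8% of 163 genes, against 82.6% and 76.7% of 4851 genes further inside. Set1 deletion peaks were at 3 of the 251 genes with each antibody (1.20%), against 5.05% and 3.55% further inside. Genes with no standard name carried peaks of H3K4me2 in 296 of 745 cases (39.7%) and of H3K4me3 in 225 (30.2%), against 80.1% and 74.2% of the 5257 named genes.

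Auxotrophic marker genes gave values that stand apart. The standard strain BY4741 lacks URA3, LEU2 and MET17 and carries a partial deletion of HIS3, and whether the BY4741A of the labels has the same genotype was not tested. LEU2 and MET17 had no peak in any of the 4 lists. URA3 (YEL021W, chromosome V, 116167 to 116970) had a wild-type H3K4me3 peak from 116062 to 116940 at score percentile 98.7, a set1 deletion H3K4me2 peak at percentile 1.29, and no listed wild-type H3K4me2 peak, at a place where peak numbers were skipped. HIS3 (YOR202W, chromosome XV, 721946 to 722608) had set1 deletion peaks with both antibodies, at percentiles 60.6 and 71.3, and no listed wild-type peak, again where numbers were skipped in both wild-type lists. SDC1 likewise lay where H3K4me2 peak numbers were skipped. The labels give no plasmid or marker of these strains.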
